A study of Homo sapiens with 9 samples.

How the data were processed

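RNA sequencing counts of 9 human tissue samples were analysed, 3 of normal skin and 6 of burn eschar, grouped by the tissue named in the labels. Replicate numbers only name the samples and pair none of them. Per the labels' protocols, total RNA was extracted with a column kit, its quality was checked by capillary electrophoresis and libraries followed standard Illumina procedures. The submitters' processing notes name bcl2fastq, TopHat and edgeR, without versions or roles, and the genome build hg19. The deposited values are whole-number read counts per Entrez gene, not normalized, as their differing totals show. The counting program, the gene annotation, the strand setting and any filter are not given in the sources used here. Reads of overlapping or antisense genes and of near-identical copies therefore cannot be assigned with certainty.

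The deposited table has 27380 rows, of which 27252 Entrez IDs matched a gene symbol in a RefSeq gene table of the GRCh38 assembly, used for names only. The other 128 held 0.079% to 0.153% of the reads of a library. XIST, TSIX and Y-linked genes (116 rows) were left out because the samples come from people, which left 27264 rows. Pairs of libraries of one group differed by far more than sampling noise (chi-square per degree of freedom 71.4 to 425.3), so no library was counted as a repeat of another. This does not show that the libraries came from separate donors. Total counts were 28085583, 19859983 and 18412478 reads in normal skin 1 to 3 and 18946124, 18251320, 21600097, 17841114, 9457279 and 22058288 reads in eschars 1 to 6. Intervals and floors cover counting error only, since PCR copies were not marked by molecular identifiers in the sources used here.

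Genes were kept by filterByExpr with the group (17502 genes) and normalized by TMM, and eschar was compared with normal skin by the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3. Genes were called at a Benjamini-Hochberg adjusted p below 0.05. The common dispersion was 0.384. The standard error of a log2 fold change is its size over the square root of F. Levels are CPM (read counts scaled to library size) after TMM, given as mean ± SD over 3 normal skin and 6 eschar libraries. A fold against a group with 0 reads is a lower bound computed with 3 reads over the group as the floor. For 1 to 3 reads the ratio of CPM carries an exact 95% interval from the binomial distribution of the reads. At most 1 gene of a list had a group with 0 reads. Setting it to its bound could hardly move a median, and it moved none.

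Before the data were examined, 38 gene lists, the tests, the alternatives and the rule for naming genes were fixed. Of 703 list entries 687 were found. The list of mitochondrially encoded genes was not analysed here, and 37 lists were tested. Lists were compared with all other genes by camera of limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01 between genes and again with an estimated correlation. They were also tested by fry, which does not compare a list with other genes. In addition the mean log2 CPM of each list was compared between groups by an exact two-sided permutation test over the 84 splits of 9 samples into 3 and 6, whose smallest p is 0.0119. Genes were named as follows: the 10 largest increases and the 10 largest decreases among called genes with a mean of at least 5 CPM in the higher group and no overlap between groups; in each list up to 4 called genes with the smallest adjusted p, filled up to 2 with the most abundant members; and a fixed set of skin, matrix, inflammation and blood genes. Some genes that the rule picks are not reported here. Other genes are said to have been chosen after their values were seen.

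The procedure was tested on simulated data with the means, library sizes and dispersions of the 17502 genes, of which 50 each were changed by 2, 4, 8 or 16-fold. It recovered 4%, 18%, 44% and 54% of these, and 4.76% of its calls were false. A changed list was called by camera and 0 of 30 unchanged lists were. The simulated genes were independent of one another, and in the other splits of the real samples a median of 16 lists was called, so this does not describe these data. The simulation also changed far fewer genes than the 3213 called in the real data, which makes its adjusted p stricter. The recovered shares therefore do not carry over to these data. An uncalled gene is still not shown to be unchanged. Alternatives were DESeq2 1.42.0, its size factors or upper-quartile factors in edgeR, no filter or a filter of 1 CPM in 3 samples, a robust dispersion fit, limma-voom with sample weights, a test against a 2-fold change, other prior counts, medians in place of means, other gene sets for the principal components, and each library left out in turn. Samples far from their group were sought among the 6 eschars with Dixon's ratio (limit 0.625), on list scores and on log2 of CPM plus 0.5; the 3 normal samples were too few for it. Python 3.11.15, with SciPy 1.17.1 and matplotlib 3.10.9, was used for the closing tests and the figures.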

Results

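Gene expression was measured by RNA sequencing of total RNA in 9 human tissue samples, 3 of discarded normal skin and 6 of burn eschar, the dead and damaged tissue that covers a deep burn. The deposited table holds read counts per gene. Total counts ran from 18412478 to 28085583 reads in the 3 normal skin libraries and from 9457279 to 22058288 reads in the 6 eschar libraries. The shallowest was eschar 5, with 9457279 reads and 15094 genes detected, against 18557 to 20536 genes in the other 8 libraries. Nothing in the labels says that the samples came from separate donors or that any eschar was paired with a normal sample. The p-values below therefore measure only the spread between these samples, which may be technical.

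The single comparison of the design asks how the transcriptome of burn eschar differed from that of normal skin. In eschar 24 of 27 genes of the cornified layer and 7 of 10 melanocyte genes were lower. Higher were 16 of 21 neutrophil genes, 17 of 20 macrophage genes (1 was lower), 16 of 26 inflammatory cytokine genes and 12 of 21 genes of metalloproteinases and the plasminogen system. By limma-voom with sample weights these numbers were 11, 16, 11 and 11, and by DESeq2 18, 19, 18 and 14. Of 37 lists 0 were called as lists by camera with an estimated correlation between genes, and by fry 6 were higher and 3 lower. With the preset correlation 15 were higher and 6 lower, but a median of 16 lists was called in other splits of the samples. By mean level 0 passed. Even the 8 lists at the smallest possible p of the exact permutation test (0.0119) had an adjusted p of 0.0551. Lists at that p pass or fail together, depending on how many reach it, so the 0 carries little weight. Of 17502 genes tested, 1718 were higher and 1495 lower in eschar by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05. Among them 494 higher and 595 lower genes changed at least 8-fold. In 27.0% of tested genes the 6 eschars did not overlap the 3 normal samples, against 2.38% expected by chance. The counts fell with any 1 of the 3 normal samples left out, which also lowers the power of the test. Lost power was not separated from the effect of the sample itself, here or for single genes below. The counts were 739 higher and 742 lower without normal skin 1, 691 and 763 without normal skin 2 and 953 and 991 without normal skin 3. Without eschar 5 they were 2631 and 2245.

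The first principal component held 48.0% of the variance and placed all normal samples below all eschars (exact two-sided permutation test, p = 0.0119, the smallest that 3 against 6 samples can give). Eschar 5 lay apart from the other eschars at 257.6 on this component, against 15.4 to 51.6 for those. With a prior count of 0.5 in place of 2 the exact p was 0.0595. Spearman correlations between libraries were 0.956 to 0.969 within normal skin, 0.801 to 0.950 within eschar and 0.693 to 0.840 between the groups.

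**Figure D1:**
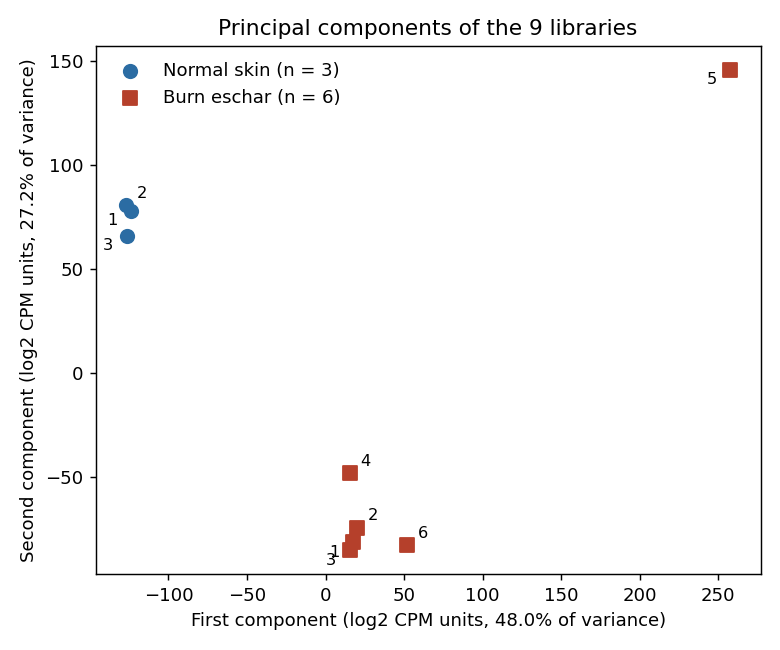
Scores of the 9 libraries on the first component (x axis, 48.0% of variance) and the second (y axis, 27.2% of variance), from log2 CPM of 17502 genes; circles are normal skin, squares are eschar and the digits are replicate numbers. Eschar 5 sits alone at 257.6 on the first component.

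Genes of the outer epidermis were far lower in eschar. KRT1 (Entrez 3848), a keratin of the suprabasal epidermis, fell from 19426 ± 7289.7 to 8.16 ± 2.86 CPM (SD, n = 3 and 6; log2 fold change -11.22, SE 0.60, edgeR adjusted p = 1.1e-05). Its partner KRT10 (Entrez 3858) fell from 25704 ± 6667 to 40.1 ± 14.6 CPM (log2 fold change -9.32, SE 0.55, edgeR adjusted p = 2.1e-05). Filaggrin, FLG (Entrez 2312), which bundles keratin in the granular layer, fell from 5367 ± 996 to 4.08 ± 2.08 CPM (log2 fold change -10.37, SE 0.56, edgeR adjusted p = 1.1e-05). LORICRIN (Entrez 4014), the main cornified envelope protein, fell from 1018 ± 319 to 0.524 ± 0.224 CPM (log2 fold change -10.93, SE 0.50, edgeR adjusted p = 7.2e-06). Of 27 tested genes of the cornified envelope and terminal differentiation, 24 fell, 0 rose and 3 were not called, and 26 fell when adjusted over the list alone. The list's median log2 fold change was -8.04 (camera adjusted p = 3.0e-26, and adjusted p = 0.164 with an estimated correlation). The late cornified envelope genes LCE2B, LCE1B and LCE1C also fell, with log2 fold changes of -11.75, -11.57 and -10.88. LCE2C, LCE5A and LCE2D fell to 1, 2 and 2 reads over all 6 eschars, so their ratios of normal skin to eschar were 10483 (95% counting interval 1881 to 414110), 3119 (863 to 25763) and 2709.9 (749.6 to 22386). LCE5A was at 115 CPM in normal skin 2 and at most 36.8 CPM in the other normal samples. Genes of this cluster are close copies of one another, and how the counting divided shared reads is not given. MSMB, a secreted protein of mucosal glands, had 0 reads in all eschars and was at least 618-fold lower there (floor of 3 reads over the group). Its level in normal skin 1 to 3 was 6.92, 1.13 and 49.3 CPM, so the bound rests mostly on normal skin 3. Of 16 enzymes of barrier lipid synthesis 11 fell and 0 rose, and 12 fell when adjusted over the list alone (camera adjusted p = 4.1e-07, and adjusted p = 0.291 with an estimated correlation). Among them were ELOVL4, which lengthens fatty acids (log2 fold change -4.14, SE 0.40, edgeR adjusted p = 3.3e-04), and the lipoxygenase ALOXE3 (log2 fold change -6.40, SE 0.98, edgeR adjusted p = 0.00268).

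Most melanocyte genes were lower as well. Of 10 melanocyte genes 7 fell and 0 rose, and 7 fell when adjusted over the list alone, with a median log2 fold change of -5.40 (camera adjusted p = 8.1e-07, and adjusted p = 0.291 with an estimated correlation). The melanin enzyme DCT fell from 414 ± 189.7 to 3.29 ± 6.35 CPM (log2 fold change -6.96, SE 1.27, edgeR adjusted p = 0.00555). The melanocyte channel gene TRPM1 fell from 23.8 ± 10.1 to 0.519 ± 0.461 CPM (log2 fold change -5.47, SE 0.69, edgeR adjusted p = 0.00111). CD207, which encodes langerin of Langerhans cells, fell from 74.9 ± 3.19 to 0.262 ± 0.226 CPM (log2 fold change -8.10, SE 0.70, edgeR adjusted p = 1.7e-04). The list of 11 dendritic and Langerhans cell genes was not called (camera adjusted p = 0.166): 2 fell, CD207 and CD1A, and 1 rose, CCR7, a receptor of migrating dendritic cells, while 1 rose and 4 fell when adjusted over the list alone. CD1A and CCR7 lost their calls without normal skin 1 or 2, with adjusted p of up to 0.0636 and 0.0659. Without eschar 5, 4 genes of this list fell and 2 rose.

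Basal keratinocyte genes changed less and varied between eschars. Of 14 genes 3 fell and 0 rose, and 3 fell when adjusted over the list alone, with a median log2 fold change of -0.83 (camera adjusted p = 0.00674, and adjusted p = 0.733 with an estimated correlation). These were DST, KRT15 and TP63, the transcription factor of the basal layer (log2 fold change -3.74, SE 1.01, edgeR adjusted p = 0.0292). None of them kept its call without normal skin 1 or without normal skin 2, and 1 did without normal skin 3. KRT14, chosen after its values were seen, was at 4692 ± 1412 CPM in normal skin and 877 ± 1029 CPM in eschar (SD; log2 fold change -2.42, SE 1.53, edgeR adjusted p = 0.319). It was at 1201, 2499 and 1488 CPM in eschars 1, 2 and 4 and 3.96 and 3.17 CPM in eschars 5 and 6. Every eschar was thus below the lowest normal sample (3070 CPM), although KRT14 was not called. The 19 wound-activated keratinocyte genes were not called as a list (camera adjusted p = 0.122), with 0 higher and 1 lower, SPRR2B, and 0 rose and 1 fell when adjusted over the list alone. SPRR2B lost its call without normal skin 3 (adjusted p = 0.0878), and 4 genes of the list fell without eschar 2. KRT16, a keratin induced by wounding, was at 54.8 ± 34.9 CPM in normal skin and 158 ± 259.7 CPM in eschar (log2 fold change 1.53, SE 1.85, edgeR adjusted p = 0.620). Sweat gland genes (1 of 11 rose, KRT7; camera adjusted p = 0.274) and hair follicle and sebaceous gland genes (2 of 13 rose, FADS2 and FAR2; camera adjusted p = 0.827) were not called as lists. The sweat peptide gene DCD was at 0.230 ± 0.398 CPM in normal skin and 45.7 ± 92.7 CPM in eschar (log2 fold change 7.69, SE 3.12, edgeR adjusted p = 0.119; DESeq2 adjusted p = 0.0263). Adjusted over the list alone, 1 sweat gland gene rose, and 2 follicle and sebaceous genes rose and 1 fell. KRT7, FADS2 and FAR2 lost their calls without normal skin 2, FAR2 also without normal skin 1 or eschar 2 or 4, and without eschar 4 the latter list had 1 gene higher and 3 lower. The follicle and sebaceous list had a median log2 fold change above 0 and a mean log2 level that was lower in eschar (-0.28).

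**Figure D2:**
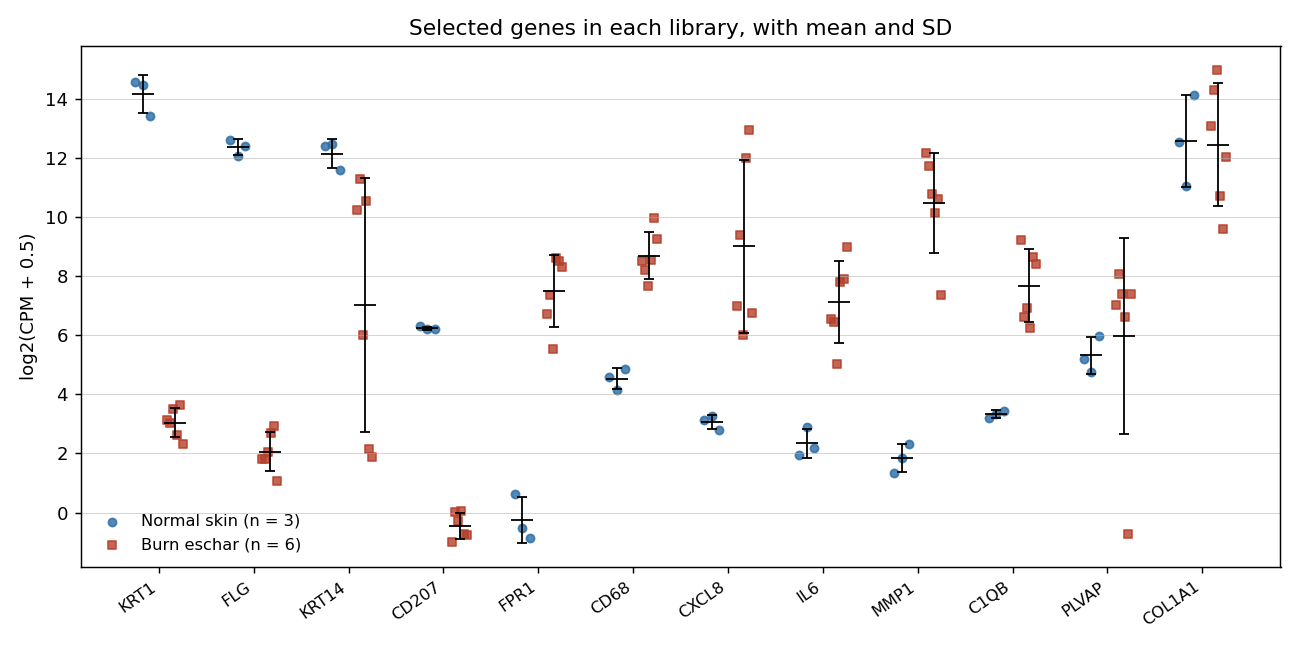
Level of 12 genes in each library, as log2 of CPM (read counts scaled to library size) plus 0.5, for normal skin (circles) and eschar (squares), with mean and SD as bars; the genes were chosen after their values were seen. KRT1, FLG, CD207 and KRT14 are lower in every eschar than in every normal sample, though KRT14 was not called. FPR1, CD68, CXCL8, IL6, MMP1 and C1QB are higher in every eschar. PLVAP is at 0.110 CPM in eschar 5.

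Most neutrophil genes were higher in eschar. Of 21 neutrophil genes 16 rose, 0 fell and 5 were not called, and 18 rose when adjusted over the list alone, with a median log2 fold change of 6.96 (camera adjusted p = 7.1e-12, and adjusted p = 0.291 with an estimated correlation). FPR1, the receptor for bacterial formyl peptides, rose from 0.432 ± 0.538 to 231 ± 145 CPM (SD, n = 3 and 6; log2 fold change 8.97, SE 1.21, edgeR adjusted p = 0.00146). CSF3R, the receptor of granulocyte colony-stimulating factor, rose from 1.71 ± 0.912 to 396 ± 465 CPM (log2 fold change 7.84, SE 1.37, edgeR adjusted p = 0.00468), with 1300.1 CPM in eschar 5. MMP8, the neutrophil collagenase, had 0 reads in all normal samples and was at least 545-fold higher in eschar, with 90.4 and 36.5 CPM in eschars 1 and 2 and at most 7.24 CPM in the others. Its call was lost with any 1 normal sample or eschar 2 left out, and in limma-voom with sample weights (adjusted p of up to 0.103). The eosinophil ribonuclease RNASE2 and the receptors FCGR1A and LILRA3, also at 0 in normal skin, were at least 400.1-fold, 249.8-fold and 266-fold higher, FCGR1A with 37.7 CPM in eschar 5. MS4A6E was at least 412-fold higher, with 30.9 and 59.3 CPM in eschars 1 and 6 and at most 6.92 CPM in the others. Its call was lost without normal skin 1, 2 or 3 or eschar 1 (adjusted p of up to 0.0947). FCGR1A has near-identical copies, so its reads are uncertain. CD177, a neutrophil surface protein with 3 reads in normal skin, had a ratio of eschar to normal skin of 976 (95% counting interval 334 to 4733) and lost its call in limma-voom with sample weights (adjusted p = 0.122). S100A8, an abundant neutrophil protein, was at 35.3 ± 45.5 CPM in normal skin and 602 ± 398 CPM in eschar and was not called by edgeR (log2 fold change 4.09, SE 1.39, edgeR adjusted p = 0.0697), but was by DESeq2 and limma-voom (adjusted p = 0.00111 and 0.0181). Its partner S100A9, chosen after its values were seen, rose (log2 fold change 4.62, SE 1.42, edgeR adjusted p = 0.0480).

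Of 20 monocyte and macrophage genes 17 rose and 1 fell, and 19 rose and 1 fell when adjusted over the list alone, with a median log2 fold change of 4.32 (camera adjusted p = 4.2e-12, and adjusted p = 0.291 with an estimated correlation). CD68 rose from 23.1 ± 5.64 to 476 ± 290.4 CPM (log2 fold change 4.36, SE 0.59, edgeR adjusted p = 0.00143). The scavenger receptor MSR1 rose from 6.10 ± 2.80 to 136 ± 64.7 CPM (log2 fold change 4.48, SE 0.54, edgeR adjusted p = 9.6e-04). The gene that fell, GPNMB, was chosen after its values were seen (log2 fold change -1.31, SE 0.34, edgeR adjusted p = 0.0249) and is also expressed by melanocytes. Without normal skin 2 the number of neutrophil genes that rose was 9, and without normal skin 1 or 2 that of macrophage genes was 11, with GPNMB no longer called without normal skin 1 or 2 or eschar 1. Of 18 T and NK cell genes 3 rose (CD4, IL7R and LCK) and 0 fell, and 4 rose when adjusted over the list alone (camera adjusted p = 0.00544, and adjusted p = 0.591 with an estimated correlation). CD4 is also expressed by macrophages (log2 fold change 2.40, SE 0.42, edgeR adjusted p = 0.00451). Of 12 B and plasma cell genes 3 rose (CD79A, MS4A1 and MZB1) and 0 fell, and 9 rose when adjusted over the list alone, with a median log2 fold change of 5.29 (camera adjusted p = 0.00103, and adjusted p = 0.685 with an estimated correlation). IL7R and LCK lost their calls without normal skin 1 or 3, and LCK also without normal skin 2 or eschar 2, 3 or 4. No B cell gene kept its call with any 1 normal sample left out, 1 was called without eschar 1, 2 or 4 and 10 were called without eschar 5. MS4A1 also lost its call in limma-voom with sample weights. T and NK cell genes that rose numbered 1 without normal skin 1 or 3 and 8 without eschar 5.

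Mast cell and erythroid genes were not detectably different. Of 10 mast cell genes 0 were called by edgeR, with 0 at an unadjusted p under 0.05, 0 by DESeq2 and 1 lower by limma-voom (camera adjusted p = 0.328), and the list's median (0.12) and mean (-0.11) differed in sign. Of 4 erythroid genes 0 were called by edgeR, DESeq2 or limma-voom, and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.658). Haemoglobin HBB was at 45.0 ± 67.9 CPM in normal skin and 41.5 ± 45.9 CPM in eschar (SD, n = 3 and 6). Adjusted over the list alone, 0 genes of either list rose or fell. Of 6 platelet genes 2 rose, PPBP and ITGB3, and 1 fell, GP1BA, with the same numbers when adjusted over the list alone (camera adjusted p = 0.524). None of these kept its call without normal skin 1 or 2, and GP1BA also lost it without normal skin 3 or eschar 1, 3, 4 or 6. PPBP also lost its call without normal skin 3 or eschar 2 or 4, and in limma-voom with sample weights.

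Inflammatory mediators were higher in eschar. Of 26 cytokine and chemokine genes 16 rose and 0 fell, and 19 rose when adjusted over the list alone, with a median log2 fold change of 5.61 (camera adjusted p = 3.8e-09, and adjusted p = 0.310 with an estimated correlation). The neutrophil-attracting chemokine CXCL5 rose from 0.569 ± 0.584 to 861 ± 1115 CPM (SD, n = 3 and 6; log2 fold change 10.59, SE 2.10, edgeR adjusted p = 0.00797), with 2912 CPM in eschar 5. CXCL6 rose from 0.459 ± 0.488 to 114 ± 97.9 CPM (log2 fold change 7.99, SE 1.21, edgeR adjusted p = 0.00255). The cytokine IL6 rose from 4.78 ± 1.89 to 197 ± 173 CPM (log2 fold change 5.37, SE 0.95, edgeR adjusted p = 0.00488). CXCL8 rose from 7.95 ± 1.37 to 2171 ± 3235 CPM (log2 fold change 8.09, SE 2.11, edgeR adjusted p = 0.0257), with 7953 CPM in eschar 5. IL1B rose from 6.06 ± 4.50 to 737 ± 1095 CPM (log2 fold change 6.92, SE 1.97, edgeR adjusted p = 0.0361), with 2848 CPM in eschar 5. Both lost their calls with any 1 normal sample left out, with adjusted p of up to 0.105 for CXCL8 and 0.140 for IL1B. IL1B also lost its call without eschar 2 or 4, and in limma-voom with sample weights. Without normal skin 1, 2 or 3 the cytokine genes that rose numbered 9, 7 and 9. SAA1, LBP and HP were among the 10 largest increases chosen by the naming rule. SAA1 rose from 0.0951 ± 0.0936 to 121 ± 147 CPM (log2 fold change 10.12, SE 2.65, edgeR adjusted p = 0.0260), with 363 CPM in eschar 1. LBP and HP, with 3 and 1 reads in normal skin, had ratios of eschar to normal skin of 1815 (95% counting interval 621 to 8804) and 1276 (229 to 50441). LBP was at 262 CPM in eschar 6 and 0.110 CPM in eschar 5. SAA1 and LBP lost their calls with any 1 normal sample left out, and in limma-voom with sample weights (adjusted p of up to 0.346 and 0.126 over all alternatives). HP lost its call without normal skin 1 (adjusted p = 0.0506).

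Of 16 complement genes 7 rose and 0 fell, and 9 rose when adjusted over the list alone, with a median log2 fold change of 1.55 (camera adjusted p = 2.6e-04, and adjusted p = 0.310 with an estimated correlation). C1QB rose from 9.60 ± 0.862 to 272 ± 209 CPM (log2 fold change 4.82, SE 0.81, edgeR adjusted p = 0.00391). The anaphylatoxin receptor C5AR1 rose from 5.28 ± 3.43 to 408 ± 425 CPM (log2 fold change 6.27, SE 1.23, edgeR adjusted p = 0.00750), with 1183 CPM in eschar 5. C1QA, C1QB and C1QC belong to the macrophage list too. The number that rose was 4 without normal skin 1 or 2 and 11 without eschar 5. Of 22 interferon-stimulated genes 5 rose and 0 fell, and 10 rose when adjusted over the list alone (camera adjusted p = 3.8e-05, and adjusted p = 0.685 with an estimated correlation). MX2, an antiviral GTPase, rose from 13.3 ± 2.68 to 93.0 ± 37.9 CPM (log2 fold change 2.81, SE 0.39, edgeR adjusted p = 0.00173). The transcription factor IRF7 rose from 8.79 ± 0.735 to 45.6 ± 19.2 CPM (log2 fold change 2.38, SE 0.41, edgeR adjusted p = 0.00442). Interferon genes that rose numbered 2 with any 1 normal sample left out and 3 without eschar 3.

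**Figure D3:**
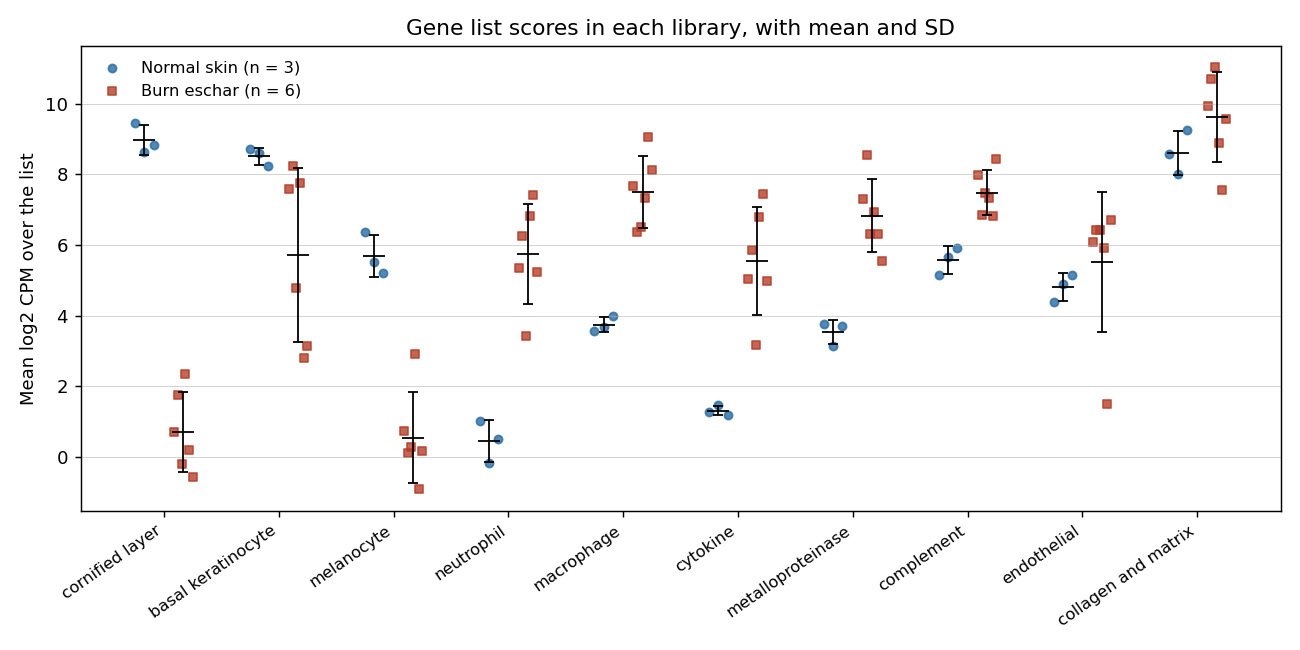
Mean log2 CPM over the genes of 10 lists in each library, for normal skin (circles) and eschar (squares), with mean and SD as bars. Cornified layer and melanocyte scores are lower, and neutrophil, macrophage, cytokine, metalloproteinase and complement scores higher, in every eschar than in every normal sample. The basal keratinocyte score is lower in every eschar too, but narrowly (8.236 in eschar 2, 8.249 in normal skin 3). The endothelial score of eschar 5 is 1.5.

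Genes that degrade the extracellular matrix were higher in eschar. Of 21 matrix metalloproteinase and plasminogen system genes 12 rose and 0 fell, and 13 rose when adjusted over the list alone, with a median log2 fold change of 4.46 (camera adjusted p = 5.5e-07, and adjusted p = 0.291 with an estimated correlation). Interstitial collagenase, MMP1 (Entrez 4312), rose from 3.20 ± 1.20 to 2096 ± 1601 CPM (SD, n = 3 and 6; log2 fold change 9.36, SE 1.24, edgeR adjusted p = 0.00134). The urokinase gene PLAU rose from 23.9 ± 8.08 to 295 ± 176 CPM (log2 fold change 3.62, SE 0.60, edgeR adjusted p = 0.00371). MMP9 rose from 5.10 ± 2.18 to 333 ± 351 CPM (log2 fold change 6.03, SE 1.30, edgeR adjusted p = 0.0113) but not without normal skin 2 or 3 (adjusted p of up to 0.0621). Without eschar 5, 1 gene of the list fell. Of 24 collagen and matrix genes 7 rose and 0 fell, and 8 rose when adjusted over the list alone (camera adjusted p = 0.0177, and adjusted p = 0.733 with an estimated correlation). Those that rose included the matrix glycoproteins THBS1 (log2 fold change 5.13 ± 1.07 (SE)), VCAN (log2 fold change 3.15 ± 0.67 (SE)) and TNC (log2 fold change 3.55 ± 0.88 (SE)), none of which was called without normal skin 1. The main fibrillar collagens were not called. COL1A1 was at 8676 ± 8282 CPM in normal skin and 11382 ± 12598 CPM in eschar (log2 fold change 0.39, SE 1.14, edgeR adjusted p = 0.853). COL3A1 was at 7902 ± 7425 CPM in normal skin and 15761 ± 15981 CPM in eschar (edgeR adjusted p = 0.603). Matrix genes that rose numbered 0, 1 and 3 without normal skin 1, 2 and 3, and 4 without eschar 1.

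Of 24 TGF-beta and activin signalling genes 9 rose and 1 fell, and 10 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.00674, and adjusted p = 0.685 with an estimated correlation). TGFB1 rose from 37.6 ± 2.45 to 113 ± 22.6 CPM (log2 fold change 1.58, SE 0.23, edgeR adjusted p = 0.00194), as did LTBP2, a binding protein of latent TGF-beta (log2 fold change 2.31, SE 0.29, edgeR adjusted p = 0.00116). Genes of this list that rose numbered 4 with any 1 normal sample left out, and TGFBR3, the gene that fell, chosen after its values were seen, lost its call with any 1 normal sample left out and without eschar 1 or 4. Of 36 WNT pathway genes 9 fell and 1 rose, and 12 fell and 3 rose when adjusted over the list alone (camera adjusted p = 0.00213, and adjusted p = 0.733 with an estimated correlation). The ligands WNT16 (log2 fold change -7.34, SE 0.68, edgeR adjusted p = 2.8e-04) and WNT3 (log2 fold change -4.98, SE 0.75, edgeR adjusted p = 0.00242) fell. The WNT target AXIN2 fell too (log2 fold change -2.38, SE 0.43, edgeR adjusted p = 0.00519), and the receptor FZD2 rose (log2 fold change 2.68, SE 0.50, edgeR adjusted p = 0.00601). WNT genes that fell numbered 5 without normal skin 1 or 3 and 14 without eschar 5, and those that rose 2 without eschar 1 and 5 without eschar 5. The WNT score of eschar 5 was -0.39 against 1.97 to 3.03 in the other eschars, and its TGF-beta score was 3.83 against 5.46 to 6.20.

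Stromal and vascular markers showed few calls. Of 18 endothelial genes 3 rose and 0 fell, with the same numbers when adjusted over the list alone (camera adjusted p = 0.0577). ENG rose from 41.1 ± 9.35 to 351 ± 138 CPM (log2 fold change 3.09, SE 0.43, edgeR adjusted p = 0.00174). PECAM1 rose from 56.6 ± 16.4 to 224 ± 59.6 CPM (log2 fold change 1.98, SE 0.31, edgeR adjusted p = 0.00274). The third, ROBO4, lost its call with any 1 normal sample left out, or without eschar 2 or 6. The endothelial score of eschar 5 was 1.5 against 5.91 to 6.72 in the other eschars, and without eschar 5 12 endothelial genes rose. Of 15 pericyte and smooth muscle genes 1 rose, ACTA2, and 0 did when adjusted over the list alone (camera adjusted p = 0.328). ACTA2 was called without eschar 4 or 5 but not without any other library, and 5 genes of the list rose without eschar 5, whose score was 1.78 against 5.57 to 6.88. Among 16 fibroblast genes 2 rose, PDGFRA (log2 fold change 1.87, SE 0.34, edgeR adjusted p = 0.00524) and THY1, and 2 fell, CLEC3B (log2 fold change -2.79, SE 0.50, edgeR adjusted p = 0.00531) and APCDD1, with the same numbers when adjusted over the list alone (camera adjusted p = 0.511). THY1 lost its call with any 1 normal sample left out, and APCDD1 without any 1 library other than eschar 5.

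Of 19 adipocyte genes 2 rose, CD36 and LGALS12, and 0 fell, and 10 rose when adjusted over the list alone (camera adjusted p = 0.00722, and adjusted p = 0.733 with an estimated correlation). Neither count was stable: the number that rose was 0 with any 1 normal sample left out, or without eschar 1 or 3, 1 without eschar 4 or 6, 6 without eschar 2 and 8 without eschar 5, which also gave 1 that fell. ADIPOQ was at 1.24 ± 0.593 CPM in normal skin and 57.7 ± 103 CPM in eschar (log2 fold change 5.54, SE 2.01, edgeR adjusted p = 0.0858; DESeq2 adjusted p = 0.000546), with 264 CPM in eschar 6. Of 8 skeletal muscle genes 3 fell, TNNI2, TNNT1 and NEB, and 3 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.454). The numbers that fell were 1 without normal skin 1 and 0 without normal skin 2, and 1 gene rose without eschar 3. Of 12 Schwann cell and nerve genes 1 fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 0.0826).

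Of 20 endoplasmic reticulum stress genes 13 rose and 0 fell, and 14 rose when adjusted over the list alone, with a median log2 fold change of 1.28 (camera adjusted p = 3.2e-06, and adjusted p = 0.454 with an estimated correlation). The chaperone HYOU1 rose from 54.9 ± 5.87 to 190.2 ± 65.3 CPM (SD, n = 3 and 6; log2 fold change 1.79, SE 0.34, edgeR adjusted p = 0.00623). HSP90B1 rose from 413 ± 63.8 to 1619 ± 726 CPM (log2 fold change 1.97, SE 0.42, edgeR adjusted p = 0.0109). The number that rose was 3, 1 and 5 without normal skin 1, 2 and 3, and HSP90B1 was not called without normal skin 1 or 2 (adjusted p of up to 0.0651). Of 14 heat shock genes 4 rose and 1 fell, and 5 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.266). The small heat shock gene HSPB1, abundant in keratinocytes, fell from 491 ± 42.9 to 121 ± 64.1 CPM (log2 fold change -2.02, SE 0.39, edgeR adjusted p = 0.00710). Heat shock genes that rose numbered 1 without normal skin 1, 0 without normal skin 2 or 3 and 2 without eschar 1, 4 or 6. Of 26 hypoxia and glycolysis genes 5 rose and 3 fell, and 9 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.0300, and adjusted p = 0.794 with an estimated correlation). The lactate transporter SLC16A3 rose from 3.50 ± 1.53 to 119 ± 74.5 CPM (log2 fold change 5.09, SE 0.72, edgeR adjusted p = 0.00184). EGLN3, an oxygen-sensing hydroxylase, fell from 182 ± 12.2 to 8.09 ± 3.91 CPM (log2 fold change -4.49, SE 0.39, edgeR adjusted p = 1.7e-04). VEGFA was at 46.4 ± 17.1 CPM in normal skin and 197 ± 187 CPM in eschar (log2 fold change 2.08, SE 0.79, edgeR adjusted p = 0.0967) and was not called by edgeR, but was by DESeq2 and limma-voom (adjusted p = 0.0259 and 0.0459). Hypoxia genes that rose numbered 1 with any 1 normal sample left out and 11 without eschar 3, and those that fell 1 without normal skin 1.

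Of 9 metallothioneins 2 rose, MT2A and MT1L, and 4 rose when adjusted over the list alone (camera adjusted p = 0.0310, and adjusted p = 0.733 with an estimated correlation); these genes are close copies of one another. None was called with any 1 normal sample left out, or without eschar 1 or 6, and 4 were without eschar 3. Of 22 proliferation genes 5 rose and 0 fell, and 5 rose when adjusted over the list alone (camera adjusted p = 6.8e-05, and adjusted p = 0.685 with an estimated correlation), among them RRM2, a subunit of ribonucleotide reductase (log2 fold change 2.56, SE 0.53, edgeR adjusted p = 0.00996). They numbered 0 without normal skin 1 or 2, 1 without normal skin 3 and 2 without eschar 1 or 2. Of 38 cytosolic ribosomal protein genes 2 fell, RPLP1 and RPL18, and 0 when adjusted over the list alone, with 17 lower at an unadjusted p under 0.05, 14 lower by DESeq2 and 25 by limma-voom. All had negative log2 fold changes, with a median of -0.67 (camera adjusted p = 3.0e-07, and adjusted p = 0.733 with an estimated correlation). Those that fell numbered 0 without normal skin 1 or 2 or eschar 2 or 4, 1 without normal skin 3 or eschar 1 or 3, and 12 without eschar 6. Of 37 nuclear-encoded respiratory chain genes 0 were called by edgeR, also when adjusted over the list alone, with 2 higher at an unadjusted p under 0.05, 1 higher by DESeq2 and 2 by limma-voom (camera adjusted p = 0.328). ATP5F1B was at 426 ± 85.8 CPM in normal skin and 423 ± 96.8 CPM in eschar, and 1 gene of the list rose without eschar 3. Of 8 nuclear-retained RNAs 0 were called by edgeR, also when adjusted over the list alone, with 1 higher at an unadjusted p under 0.05, 1 higher by DESeq2 and 2 lower by limma-voom (camera adjusted p = 0.852), and 1 fell without eschar 5. Of 10 histone genes 1 rose, H2AZ1, and 3 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.954). H2AZ1 lost its call without any 1 library other than eschar 3 or 5, while 3 histone genes rose without eschar 3 and 1 fell without eschar 5 or 6. The camera direction was lower for the nuclear-retained list, whose median and mean were above 0, and for the histone list, whose mean was above 0.

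With the sample as the unit, 0 of 37 lists passed an adjusted p of 0.05 in the exact two-sided permutation test of the mean list level, and 13 had an unadjusted p under 0.05. The 8 lists at the smallest exact p of 0.0119 (adjusted p = 0.0551) were those of the cornified layer, barrier lipids, melanocytes, neutrophils, macrophages, metalloproteinases, cytokines and complement. Without eschar 5, 14 lists passed. By camera 15 lists were higher and 6 lower, and 0 were called with an estimated correlation, where 6 had an unadjusted p under 0.05. By fry, which does not compare a list with other genes, 6 lists were higher and 3 lower.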

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

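The tests of explanations in this part were chosen after the results were seen. Among the 6 eschars, 17 of 178 values had 1 library far from the other 5, where chance alone gives about 1 in 20, and 10 of the 17 were in eschar 5. 2 of those 10 were its reads and its number of genes detected. The other values are log2 of CPM plus 0.5 for genes and mean log2 CPM for lists. In eschar 5 the scores were low for endothelial genes (1.5), pericyte and smooth muscle genes (1.78), WNT genes (-0.39) and TGF-beta genes (3.83). APCDD1 (0.86) and WNT3 (-0.71) were low there, and LYZ (10.75) and KRT2 (2.8, the others 0.37 to 1.0) were high.

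Eschar 5 had 9457279 reads and 15094 genes detected, against 17841114 to 22058288 reads and 19727 to 20536 genes in the other eschars. Depth alone is argued against, because with every library thinned to its depth the other 8 still had 18393 to 19675 genes, against 15094 in eschar 5. Random loss of molecules is argued against as the whole source of the low stromal genes, because stromal markers of at least 20 CPM were shifted against neutrophil and macrophage markers by -5.57 on the log2 scale, with -1.29 to 3.21 in the other eschars. Eschar 5 was also the lowest eschar for the lists of T and NK cells (0.53), B and plasma cells (-1.36), mast cells (-0.65) and dendritic cells (-0.03), and no biological explanation was tested. For genes of 0.1 to 1 CPM, 58.1% were at 0 at equal depth, against 7.73% to 14.5% in the other eschars. The share was 44.0% at 1 to 5 CPM (1.48% to 3.81% in the others) and 15.2% at 5 to 20 CPM (0.0508% to 0.449%). Lost molecules and absent cells cannot be told apart by these shares, because both give zeros.

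Cornified genes fell further than basal keratinocyte genes. The cornified score minus the basal score differed by -5.47 between eschar and normal skin (exact two-sided permutation test, p = 0.0119, the smallest possible). In eschars 1 to 4 a loss of all keratinocytes in one proportion is argued against, because the median log2 change of cornified genes minus that of KRT5 and KRT14 was -6.46 to -2.33, with -0.25 to 0.15 in normal skin. In eschars 5 and 6 that difference was 0.04 and 1.23 but the list scores differed by -2.61 and -3.70 (0.03 to 0.73 in normal skin). Loss in equal proportion cannot be told apart from unequal loss there, since the basal list also holds genes of other cells. Levels were also low there, which limits how far a gene can be seen to fall. KRT5 was at 25.6 and 6.28 CPM, KRT14 at 3.96 and 3.17 CPM, and the cornified score at 0.18 and -0.57. Activation of remaining keratinocytes stays open, as the wound-activated score minus the basal score was higher by 1.001 with an exact p of 0.381.

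Reads of cornified genes were found in every eschar, for KRT1 at 0.0234% to 0.0616% of its mean in normal skin. KRT10 held 41.4% to 43.0% of the reads of KRT1, KRT10, KRT2, FLG, FLG2 and LORICRIN in normal skin, 61.2% to 80.8% in the eschars other than 5 and 46.1% in eschar 5 (95% interval 42.2% to 50.1%). If all such reads had been carried over from the normal libraries, the 6 genes would have the shares of a mixture of these, but the deviance from the best mixture was 47.0 in eschar 5 and at least 186.5 in the others (95% limit 11.1), which argues against carry-over as the whole source. This takes reads as independent, and in eschar 5 about 4.24 reads per molecule would undo it; no biological explanation was tested. The mixture test was added after 2 others had been seen: the share of KRT10 alone had left eschar 5 open, and before that KRT10 was found kept, relative to normal skin, 1.91 to 8.75 times as much as KRT1.

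Other values far from their group were these. LORICRIN was -0.71 in eschar 2, against -0.04 to 0.34 in the others. The hair follicle and sebaceous gland score was 4.12 in eschar 4, against -0.23 to 1.12 in the others. DCT was 4.07 in eschar 4, against -0.35 to 0.72. In eschar 3 CSF3 was 1.43 and S100A8 5.03, against lowest values of 5.93 and 8.79 in the others. LCE2C was -0.87 in eschar 3 and SPRR2B -0.25 in eschar 2, where the other eschars had 0 reads.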

How the results depend on the processing

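All alternatives here were chosen before the data were examined, and the comparison with other splits was tested after its result was seen. No called result changed sign under any alternative; signs of uncalled results were not counted. DESeq2 called 2695 genes higher and 2260 lower, and 3203 of the 3213 edgeR calls were among them. Its adjusted p was NA for 7570 genes, 9 of them edgeR calls. limma-voom with sample weights, which gave eschar 5 a weight of 0.156, called 2959 and 3058 and shared 3157 calls, and the test against a 2-fold change called 624 and 606, as its stricter hypothesis demands. For the first 2 the cause was not tested. By DESeq2 the genes that rose numbered 14 of the interferon list, 9 of the T and NK cell list and 9 of the B and plasma cell list. They numbered 8 of the adipocyte list, 10 of the proliferation list and 11 of the hypoxia list. By limma-voom the numbers, in the same order, were 8, 9, 7, 2, 6 and 9. The other normalizations, filters and the robust fit gave counts within 1.5 times the main ones. Leaving out each library gave 691 (without normal skin 2) to 2631 (without eschar 5) higher and 742 (without normal skin 1) to 2245 (without eschar 5) lower genes. Of 119 named genes that were called, 59 kept their call in every alternative and 60 lost it in at least 1, the 2-fold test aside, which was run for counts only.

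With an estimated correlation 0 lists were higher and 0 lower, and by fry 6 were higher and 3 lower; fry does not compare a list with other genes. The lists past the threshold by their score numbered 10 with medians over members, and 0 to 14 with 1 library left out (14 without eschar 5). Lists tied at the smallest exact p share an adjusted p and pass or fail together, so these counts jump from 0. Why more lists reached that p was not tested. The exact p of the first component was 0.0595 with a prior count of 0.5, where the cause was not tested. For the number of called genes, 1 of 84 splits of the samples, the real one, gave 3213 genes, and the highest other gave 6. This is the smallest share that 84 splits can give. Every other split mixes eschar with normal skin in a group, which widens the spread there and leaves few genes to call. The splits therefore cannot exclude chance for this number. Chance is not excluded for the number of lists called with a preset correlation: 15 of 84 splits gave 21 lists or more, and the highest other gave 25. The simulation recovered 4% of 2-fold changes, but it changed far fewer genes than were called here, so that share does not carry over. Of the 1718 higher and 1495 lower genes called, 1517 and 1256 changed at least 2-fold, so some smaller changes were called too.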

Other observations

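The tests in this part were chosen after the results were seen. The genes in this paragraph were picked after their values were seen, from the most abundant called genes, and no list of them was tested. The ferritin gene FTH1 rose from 552 ± 104 to 7334 ± 5371 CPM (log2 fold change 3.73, SE 0.72, edgeR adjusted p = 0.00704). FTL rose from 474 ± 135 to 5749.8 ± 5032 CPM (log2 fold change 3.60, SE 0.81, edgeR adjusted p = 0.0136). The lysosomal protease CTSB rose from 388 ± 162 to 4276 ± 2516 CPM (log2 fold change 3.46, SE 0.65, edgeR adjusted p = 0.00611). SOD2, the mitochondrial superoxide dismutase, rose from 202 ± 53.4 to 3934 ± 1854 CPM (log2 fold change 4.29, SE 0.59, edgeR adjusted p = 0.00156). NAMPT, an enzyme of NAD synthesis, rose from 147 ± 39.5 to 2837 ± 1956 CPM (log2 fold change 4.27, SE 0.79, edgeR adjusted p = 0.00601). The haemoglobin scavenger receptor CD163 rose from 36.1 ± 18.9 to 1960.0 ± 2427 CPM (log2 fold change 5.76, SE 1.33, edgeR adjusted p = 0.0153), with 6462 CPM in eschar 5. Ferritin genes have many pseudogenes, so how their reads were divided is uncertain. Abundant genes that fell included DSP (log2 fold change -4.86, SE 1.16, edgeR adjusted p = 0.0178), PERP (log2 fold change -4.57, SE 0.86, edgeR adjusted p = 0.00616) and PKP1 (log2 fold change -4.56, SE 1.14, edgeR adjusted p = 0.0213).

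The genes of this paragraph, ADIPOQ aside, were chosen after their values were seen. Eschar 6 held fat tissue transcripts at levels not seen in the other libraries. FABP4 was there at 1623 CPM, PLIN1 at 260.3, ADIPOQ at 264 and LEP at 103 CPM, and none of these genes was called by edgeR (adjusted p = 0.0741, 0.0764, 0.0858 and 0.0735). FABP4 was also at 92.8 and 177 CPM in eschars 1 and 3, with at most 5.15 CPM in normal skin. Neither the adipocyte score of eschar 6 (6.59, the other eschars 0.85 to 3.59) nor its ADIPOQ level passed the limit of Dixon's ratio. DESeq2 did call ADIPOQ (adjusted p = 0.000546). LYVE1, a marker of lymphatic vessels and some macrophages, was at 1981 CPM in eschar 6 and 888 CPM in eschar 5, with 38.3 ± 21.2 CPM (SD, n = 3) in normal skin. It was at 307, 34.5, 42.3 and 77.4 CPM in eschars 1 to 4 and was not called by edgeR (adjusted p = 0.0994).

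3 relations between list scores were tested across the 6 eschars, with exact two-sided permutation tests over 720 pairings. That cytokine genes follow neutrophil genes is a hypothesis picked after these scores were seen. Its p-values therefore describe the relation in these eschars and are not an independent test of it. Any gene held by both lists was left out of the second. Pearson r was 0.994 (p = 0.00278, adjusted 0.00833), Spearman's rho was 0.943 (p = 0.0167), and r was 0.988 without eschars 3 and 5, the farthest from the median. Both lists might also follow one mixture of cells, which was not tested. That matrix genes are lower where neutrophil genes are higher was not established, with r of -0.788 (p = 0.0639, adjusted 0.0639), rho of -0.771 (p = 0.103) and r of -0.27 without eschars 3 and 5, so the relation rests on those samples. Basal and wound-activated keratinocyte scores, which might both follow the amount of keratinocyte RNA left, had r of 0.923 (p = 0.0347, adjusted 0.0521), rho of 0.829 (p = 0.0583) and r of 0.952 without eschars 5 and 6. This relation did not pass after adjustment for the 3 tests.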
